A study of Mus musculus with 24 samples.

How the data were processed

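RNA from uteri of ovariectomized wild-type and progesterone receptor knockout (PRKO) mice was hybridized to Affymetrix mouse arrays, 3 arrays for each of 8 groups of genotype, treatment and time. Per the extract protocol in the labels, RNA of 5 mice was pooled per genotype and treatment. The deposited values are signal intensity on a linear scale, 1 value per probe set and array. The submitters' processing notes name MAS5, the Affymetrix summarization software, and its version, its settings and the normalization between arrays are not given in the sources used here. The deposited values ran from 0 upward with no negative value, and 35 of 299712 were exactly 0. Array medians lay between 323.2 and 342.6 and 2%-trimmed means between 485.5 and 523.9, so the arrays had been brought near a common level. No detection calls were used.

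The deposited table held 12488 probe sets, of which 66 control probe sets were left out of the tests and 12422 were tested with no filter on dim signal. Each array was multiplied to a 2%-trimmed mean of 500 (factors 0.954 to 1.03), 32 was added, and log2 was taken, so fold changes of dim genes are compressed by the offset. Probe sets were named from the platform annotation, where 10833 named a single gene, 396 named several and 1193 named none. The probe sets that named a single gene covered 8251 genes, and by gene identifier 10817 of these probe sets matched the reference annotation. The genome build behind the platform's probes is not given in the sources used here, so no positions are reported.

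Group means of all 24 arrays were fitted together with limma 3.58.1 in R 4.3.3, with moderated two-sided tests and an intensity trend in the prior variance. There were 16 residual and 4.98 prior degrees of freedom, and the median standard error of a log2 fold change was 0.102. The 9 comparisons were P4 against vehicle in each genotype at each time, the genotype difference of that effect at each time, PRKO against wild type in vehicle uteri at each time, and the time difference of the wild-type P4 effect. P values were adjusted by the Benjamini-Hochberg method over all tested probe sets within a comparison, and a probe set passed at an adjusted p under 0.05. The comparisons share one estimate of the spread, and comparisons that share arrays are not independent. The median SD within a group was 0.111 to 0.147 at 4 h and 0.0767 to 0.0974 at 40 h. A shared spread therefore tends to understate errors at 4 h and to overstate them at 40 h. The replicate numbers carry no stated pairing. When deviations from the expected group level were compared between arrays of the same number, every pair of the wild-type 4 h comparison correlated above 0.1 (0.114 to 0.516). This held for no other comparison of 3 arrays with 3, and differences of effects were not examined for it. For P4 at 40 h, each P4 array also matched the vehicle array of its own number best. Those correlations were 0.0686 to 0.142 in wild-type and 0.0668 to 0.481 in PRKO uteri. A block for the replicate number was tried for every comparison.

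For gene groups, 31 lists were fixed before the data were examined, as were the comparisons, the test, the rule for named genes and most alternatives. A list was tested with camera in limma, with a preset correlation of 0.01 between genes, on the probe set of highest mean signal per gene, where at least 5 members were measured, and adjusted over the lists within a comparison. The same test with the correlation estimated from the arrays is given beside each call. The genes named are the 10 highest and 10 lowest log2 fold changes among passing probe sets that name a single gene for wild-type uteri, and the 5 highest and 5 lowest for the other comparisons. All 3 arrays of a group had to lie above all 3 of the other, a condition asked of the wild-type arrays for the genotype difference and of the 40 h wild-type arrays for the time difference. Pgr and up to 4 passing members per list were named besides.

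The ratio of 3' to 5' signal of the Gapdh and beta-actin controls was computed per array as a sign of RNA quality, and an adipose score as the mean log2 signal of the measured adipose markers. Both were compared between groups by exact two-sided permutation tests on 3 against 3 arrays, which cannot go below 0.1, with adjustment over 18 tests. The procedure was tested on 20 simulated data sets of 12422 probe sets, each with 200 changed. It recovered 74.8% of changes of log2 0.5, 98.3% of changes of 1 and 100% of changes of 2, and 4.59% of its calls were unchanged probe sets. A list of 20 genes shifted by 0.3 had an unadjusted camera p under 0.05 in 20 of 20 runs and a random list in 0. The lists of the real arrays were judged by an adjusted p, which is stricter. The simulated noise was independent between probe sets and arrays and equally wide in all groups. On the real arrays genes vary together (41.7% of the within-group variance at 4 h lay in 1 component), so these rates need not hold for them.

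Alternatives chosen beforehand for the values were offsets of 1 and 100, values as deposited, quantile normalization, and the brightest 8281 or 6211 probe sets alone. Those for the fit were no intensity trend, fits of the arrays of the same time or of the compared groups alone, and the replicate block. Those for the calls were a fold change of at least 1.5 as a second threshold, all probe sets of a list, the estimated correlation, and leaving out each array in turn. Added after the data were seen were the omission of both wild-type 4 h arrays with a high Gapdh ratio, and fits with the log2 Gapdh ratio or the adipose score as a covariate. A change of sign among values that did not pass was not counted as a reversal. For the chance of a grouping, arrays were regrouped in every other way for 3 against 3, and in 100 drawn ways for the differences of effects.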

Results

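Gene expression was measured on Affymetrix mouse arrays in uteri of wild-type mice and of mice lacking the progesterone receptor (PRKO), all ovariectomized at 6 weeks of age to remove the main source of ovarian hormones. The mice received progesterone (P4, 1 mg per mouse) or the sesame oil vehicle, and uteri were taken 4 h after a first injection, or 4 h after the fourth of 4 injections given 12 h apart, which is 40 h after the first. Genotype, treatment and time made 8 groups of 3 arrays, 24 arrays in all, and RNA of 5 mice was pooled per genotype and treatment. The labels do not say whether the 3 arrays of a group carried separate pools, so every error below describes the spread between arrays and not between mice. The median deposited signal of an array lay between 323.2 and 342.6, and the number of arrays limits the precision. In the text, a value after a gene is its log2 fold change ± standard error from 3 arrays against 3, and a gene is said to have risen or fallen where its adjusted p passed the threshold over all 12422 probe sets. Every gene named as among the largest changes had all 3 arrays of a group above all 3 of the other, which 1 of the 10 splits of 6 arrays does by chance.

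The targeted gene was examined first. The Pgr probe set gave a low signal in every group, at percentile 22.4 of the mean signals of all probe sets. Its signal was 144.7 ± 4.5 (SD, n = 3) in wild-type and 126 ± 4.48 (SD, n = 3) in PRKO vehicle uteri at 4 h, and 146.8 ± 16.1 and 129.5 ± 9.59 at 40 h. The genotype difference in vehicle uteri was −0.16 ± 0.08 at 4 h and −0.15 ± 0.08 at 40 h, with an adjusted p of 1 at both times. Pgr expression as measured by this probe set therefore does not settle the genotype labels, and the position of its probes relative to the disrupted part of the gene is not given in the sources used here.

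The first question was which transcripts a single P4 injection changed within 4 h in wild-type uteri. The retinoic acid-degrading enzyme Cyp26a1 rose furthest, from a signal of 96.81 ± 6.84 to 1036 ± 270 (SD, n = 3), a log2 change of 3.02 ± 0.16, or 8.10-fold after the offset (adjusted p = 1.21e-10). The transcriptional co-regulator Cited2 rose from 714 ± 124 to 1658 ± 61.3 (log2 change 1.19 ± 0.15), and the decoy interleukin receptor Il13ra2 rose from 63.48 ± 8.71 to 183.3 ± 69.6. In the other direction, the calcium-binding protein gene Calb1 fell from 1624 ± 251 to 571.4 ± 76.7 (−1.45 ± 0.29). S100g, which encodes another calcium-binding protein, fell from 549.7 ± 178 to 254 ± 29.1 (−0.99 ± 0.17, with −0.96 at its other probe set).

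Among the other large rises at 4 h were those of the acyl-CoA thioesterase Acot7 (1.13 ± 0.17) and the steroid-inducible kinase Sgk1 (1.09 ± 0.18). With them rose the inhibitor of epidermal growth factor receptors Errfi1 (1.09 ± 0.24, and 0.83 at its other probe set, which also passed), and the sialic acid lyase Npl (1.08 ± 0.25). The pyruvate dehydrogenase kinase Pdk3 (1.05 ± 0.15), the glutathione cycle enzyme Ggct (1.02 ± 0.09) and the kinase Bmp2k (1.00 ± 0.15) completed the 10 highest. The remaining large falls were the gap junction gene Gjb2 (−1.01 ± 0.17), the sulfotransferase Sult1d1 (−0.98 ± 0.13), the carbonic anhydrase Car2 (−0.97 ± 0.14) and the chromatin protein gene Hmga2 (−0.96 ± 0.19). The tetraspanin Tspan8 (−0.95 ± 0.17), the ephrin Efnb2 (−0.88 ± 0.13) and the phospholipase Pla2g4a (−0.75 ± 0.14) followed. For Lifr, a cytokine receptor gene, 1 probe set fell (−0.76 ± 0.16) while its other 4 probe sets lay between −0.11 and 0.08.

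Among the fixed gene lists, known progesterone targets of the uterus shifted up as a list at 4 h. Where its members were first reported was not traced. The shifts of this list, here and in the comparisons below, may therefore not be independent of these data. The list kept its call when any single array was left out. Of 30 measured members, 7 rose over all probe sets, among them Cyp26a1, Cited2, Il13ra2 and the activin-binding protein gene Fst (0.94 ± 0.21). Adjusted over the list alone, 12 rose and 1 fell. The median member change was 0.23, and camera, a test of a list against all other genes, gave an adjusted p of 5.91e-11 (adjusted p = 0.000697 with an estimated correlation). Without both wild-type arrays of high Gapdh 3'/5' ratio described below, the median was 0.181 and the list still passed (adjusted p = 4.29e-06). The hedgehog ligand gene Ihh rose on its own (0.52 ± 0.11), while its pathway list did not pass (adjusted p = 0.506).

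The other lists that passed at 4 h did so only with the preset correlation. Kallikrein genes had a median of 0.319, with 1 of 11 members, Klk1 (0.70 ± 0.16), rising over all probe sets and 5 adjusted over the list alone (adjusted p = 6.97e-05, and adjusted p = 0.18 with an estimated correlation). Retinoid metabolism genes shifted up (adjusted p = 0.0107, and adjusted p = 0.055 with an estimated correlation). The 2 of 15 members that rose, also adjusted over the list alone, were Cyp26a1 and the retinaldehyde dehydrogenase Aldh1a1 (0.67 ± 0.12, and −0.13 at its other probe set). In the shared steroid hormone response, 2 of 22 members rose, Sgk1 and Errfi1, and the same number adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.599 with an estimated correlation). Estrogen-regulated uterine genes shifted down, with 2 of 22 falling, Gjb2 and Car2, and 2 adjusted over the list alone (adjusted p = 0.00205, and adjusted p = 0.18 with an estimated correlation). Epithelium markers shifted down, with 1 of 22 falling, Tspan8, and 4 adjusted over the list alone (adjusted p = 0.0224, and adjusted p = 0.327 with an estimated correlation). These lists except the kallikreins also lost their call when single arrays were left out, with the highest adjusted p, 0.549, for epithelium markers without P4 replicate 3.

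By limma, 88 of 12422 probe sets passed at 4 h in wild-type uteri, 65 higher and 23 lower after P4, and 774 had an unadjusted p under 0.05 where 621.1 would by chance. The median absolute log2 change of the 88 was 0.642. The Gapdh 3'/5' signal ratio, a sign of RNA quality, was 3.67 in vehicle replicate 2 and 3.25 in P4 replicate 2 of this comparison, against 1.23 to 1.86 on the other 22 arrays, and without these 2 arrays 29 probe sets passed. The count was 56 without vehicle replicate 1, and 47, 41 and 138 without P4 replicates 1, 2 and 3. It was 29 when the fit held the arrays of this time alone and 10 when it held these 6 arrays alone, 5 higher and 5 lower. The 4 h arrays varied more within groups than those of 40 h, with which they share the spread in the main fit. With single arrays left out, Errfi1, Npl, Calb1, Hmga2, Lifr, Pla2g4a, Fst, Ihh and Klk1 lost their call, at an adjusted p of up to 0.354.

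**Figure D1:**
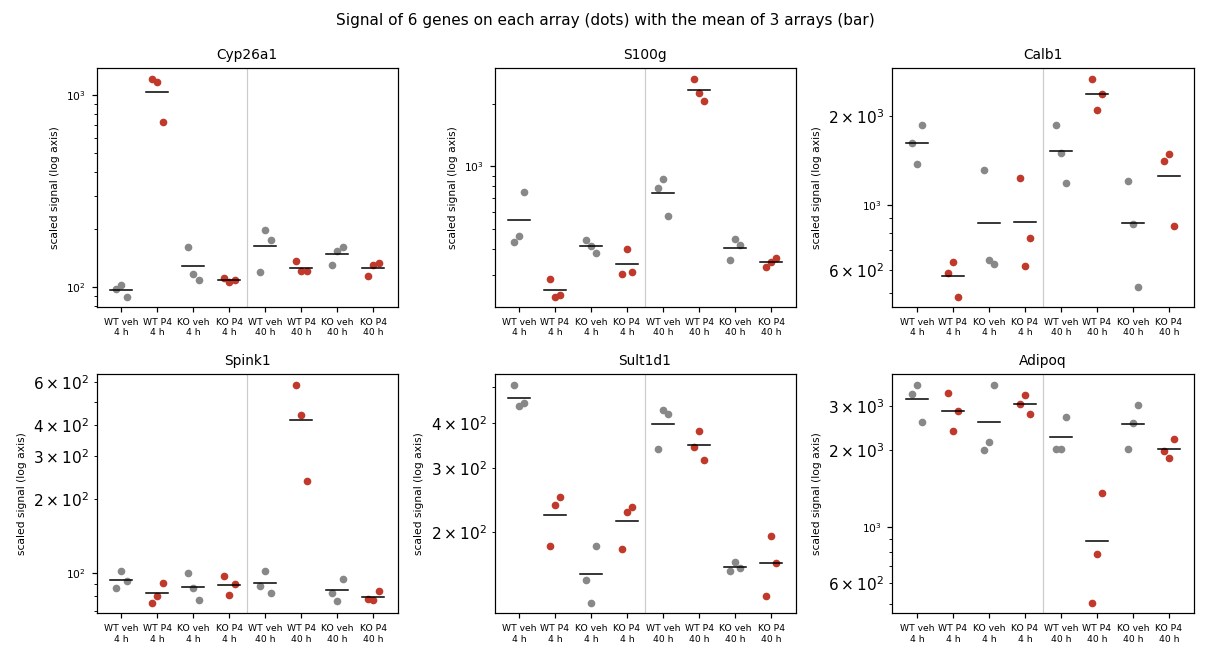
Scaled signal of 6 genes on each array, on a log axis, by genotype, treatment and time. Dots are arrays (grey vehicle, red P4) and bars are the means of 3 arrays. Cyp26a1 averaged 1036 in wild-type uteri 4 h after P4 and 126.2 at 40 h, while Spink1 averaged 82.45 and 422.

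The second question was which transcripts had changed at 40 h, after 4 injections, in wild-type uteri. Spink1, which encodes a secreted protease inhibitor, rose from a signal of 90.72 ± 9.53 to 422 ± 174 (SD, n = 3; log2 change 1.81 ± 0.17, adjusted p = 5.93e-06). S100g, which had fallen at 4 h, rose from 744.6 ± 154 to 2323 ± 285 (1.61 ± 0.17, and 1.44 at its other probe set). The itaconate-producing enzyme Acod1 rose from 327.5 ± 49.5 to 940.5 ± 121 (1.44 ± 0.15, and 0.50 at its other probe set, which also passed). The chloride channel accessory gene Clca1 fell from 1175 ± 445 to 108.6 ± 37.3 (−3.06 ± 0.47, but 0.01 at its other probe set). Adipoq, the adipocyte hormone adiponectin, fell from 2251 ± 395 to 884.4 ± 439 (−1.41 ± 0.25).

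The rest of the 10 highest changes at 40 h were Acot7 (1.68 ± 0.17), Npl (1.60 ± 0.25), the skeletal muscle actin gene Acta1 (1.52 ± 0.38) and the glutathione transferase Gstm2 (1.48 ± 0.34). They also held the prostaglandin receptor Ptger3 (1.33 ± 0.21), the vesicle coat gene Sec23b (1.15 ± 0.18) and the growth factor Igf1 (1.11 ± 0.20). A second probe set of Gstm2, Ptger3, Sec23b and Igf1 gave 0.03, 0.10, 0.02 and 0.07, none of which passed. Acta1 had a like value in PRKO uteri (1.49 ± 0.38), which did not pass there (adjusted p = 0.703). The rest of the 10 lowest were Tgfbi, a matrix protein gene (−1.73 ± 0.23, and −0.06 at its other probe set), and the lipoprotein lipase Lpl (−1.65 ± 0.39, and −1.21 at its other probe set, which passed). They were followed by the methyltransferase Inmt (−1.47 ± 0.20), the fatty acid desaturase Scd1 (−1.42 ± 0.18, and −1.03 and 0.02 at its others), the lipid droplet protein gene Cidec (−1.39 ± 0.31), the retinol carrier Rbp4 (−1.38 ± 0.21), the protease gene Adamdec1 (−1.29 ± 0.21) and the cytochrome Cyp2e1 (−1.14 ± 0.23).

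Adipose tissue markers shifted down as a list at 40 h in wild-type uteri. Of 11 measured members, 6 fell over all probe sets and 9 adjusted over the list alone, among them Adipoq, Cidec, Lpl and the carbonic anhydrase Car3 (−1.13 ± 0.18). The list median was −0.84 (camera adjusted p = 3.47e-11, and adjusted p = 0.0195 with an estimated correlation). The mean log2 signal of these markers, taken as an adipose score per array, was 8.80 ± 0.26 (SD, n = 3) after P4 and 9.59 ± 0.14 after vehicle. All 3 P4 arrays lay below all 3 vehicle arrays (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give, and 0.45 adjusted over 18 tests). Of the sterol and fatty acid synthesis list, Scd1 (−1.03 ± 0.17 at its brightest probe set) and Fasn (−0.90 ± 0.20) fell, and Rbp4 of the retinoid list fell beside them.

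Lists of connective tissue and muscle genes shifted up at 40 h, on the same arrays that had the lower adipose score. In the collagen and matrix list, 7 of 34 members rose, and adjusted over the list alone 13 rose and 1 fell. The 4 largest were Col3a1 (0.91 ± 0.16), Col1a2 (0.79 ± 0.15), Col1a1 (0.78 ± 0.14) and Col6a2 (0.77 ± 0.19). Other probe sets did not pass, at 0.81 and 0.90 for Col3a1, 0.06 for Col1a2 and 0.36 for Col1a1. The list median was 0.245 (adjusted p = 8.85e-08, and adjusted p = 0.0478 with an estimated correlation). Endometrial stroma markers, 10 of which the matrix list also holds, rose in 6 of 19 cases and in 8 adjusted over the list alone (adjusted p = 1.57e-05, and adjusted p = 0.095 with an estimated correlation). Smooth muscle markers shifted up with a median of 0.258, although none of 15 passed over all probe sets and 4 did adjusted over the list alone (adjusted p = 1.57e-05, and adjusted p = 0.00706 with an estimated correlation). With the adipose score as a covariate, a fit added after the data were seen, the medians went from 0.245 to 0.31 for matrix, from 0.333 to 0.196 for stroma and from 0.258 to 0.321 for muscle, and each list still passed camera with the preset correlation.

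The remaining lists that passed at 40 h in wild-type uteri lost their call with an estimated correlation. The shared steroid hormone response had a median of −0.312, with 1 of 22 members falling, the transcription factor gene Cebpb (−0.90 ± 0.21), and 9 adjusted over the list alone (adjusted p = 9.19e-06, and adjusted p = 0.135 with an estimated correlation). Estrogen-regulated genes fell in 3 of 22 cases, Car2 (−0.93 ± 0.14), the inhibin subunit Inhbb (−0.88 ± 0.16) and Gjb2 (−0.85 ± 0.17), and in 7 adjusted over the list alone (adjusted p = 0.00137, and adjusted p = 0.135 with an estimated correlation). Antigen presentation genes of major histocompatibility class II fell in 2 of 9 cases, Cd74 (−0.54 ± 0.13) and H2-Eb1 (−0.47 ± 0.10), and in 4 adjusted over the list alone (adjusted p = 0.00299, and adjusted p = 0.135 with an estimated correlation). Oxidative phosphorylation genes shifted up by a median of 0.11 with no single member of 29 passing, over all probe sets or adjusted over the list alone (adjusted p = 0.00345, and adjusted p = 0.245 with an estimated correlation). The hedgehog pathway shifted up by a median of 0.133 with none of 11 members passing, over all probe sets or adjusted over the list alone (adjusted p = 0.035, and adjusted p = 0.0986 with an estimated correlation). Skeletal muscle markers passed with 1 of 14 members rising, Acta1, and 3 adjusted over the list alone (adjusted p = 0.0488, and adjusted p = 0.245 with an estimated correlation). The hedgehog and skeletal muscle lists also lost their call when single arrays were left out (adjusted p up to 0.0957 and 0.107). The skeletal muscle list lost it with a block for the replicate number too (camera adjusted p = 0.0529).

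Further list members changed at 40 h although their lists did not pass. Of the progesterone targets, the endocytic receptor gene Lrp2 (1.11 ± 0.20) and the homeobox gene Hoxa11 (0.66 ± 0.14) rose beside Acod1, and Cebpb fell. Of the epithelium markers, Spink1 rose while Tspan8 (−0.93 ± 0.17) and the keratin Krt7 (−0.65 ± 0.12) fell. In the retinoid list, Aldh1a1 (−0.77 ± 0.12, and −0.015 at its other probe set) fell and the retinoic acid-binding protein gene Crabp1 (0.73 ± 0.16) rose. The endothelial tight junction gene Cldn5 (−0.79 ± 0.18), the growth factor receptor Fgfr2 (−0.53 ± 0.08 at 1 of 3 probe sets) and the protease Mmp11 (−0.46 ± 0.11) fell, and the ribosomal protein gene Rpl13a (0.56 ± 0.08) rose.

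By limma, 191 probe sets passed at 40 h in wild-type uteri, 89 higher and 102 lower after P4, with a median absolute log2 change of 0.627, and 1455 had an unadjusted p under 0.05. The Gapdh 3'/5' ratio also moved with treatment here, at 1.26 ± 0.04 (SD, n = 3) after P4 and 1.53 ± 0.06 after vehicle (exact two-sided permutation p = 0.1, the smallest possible, and 0.45 adjusted over 18 tests). With this ratio as a covariate 369 probe sets passed. With the adipose score as a covariate none passed, and 562 had an unadjusted p under 0.05, fewer than the 621.1 of chance. Over the 191 probe sets a median of 81.2% of the log2 change was then kept and 183 had the same sign, but the median standard error over all probe sets went from 0.102 to 0.178, since the score separates both groups. The changes then were 1.11 ± 0.24 for Spink1, 1.29 ± 0.28 for S100g and 0.03 ± 0.22 for Adipoq, which is part of the score. Outside the score, Rbp4 kept 25.1% and Cyp2e1 20.5% of their change. The count was 109 and 99 without vehicle replicates 2 and 3, and 110, 90 and 119 without P4 replicates 1, 2 and 3. More probe sets were then higher than lower without vehicle replicate 3 (59 and 40) or P4 replicate 1 (61 and 49) or 2 (49 and 41). It was 539 when the fit held the arrays of this time alone, which varied less within groups than those of 4 h. With single arrays left out, Acta1, Gstm2, Lpl (at 1 of its 2 probe sets), Cidec, Cyp2e1, Cebpb, Hoxa11, Gjb2, Col6a2, Cldn5, Cd74, H2-Eb1, Crabp1, Mmp11 and Fasn lost their call, at an adjusted p of up to 0.247.

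**Figure D2:**
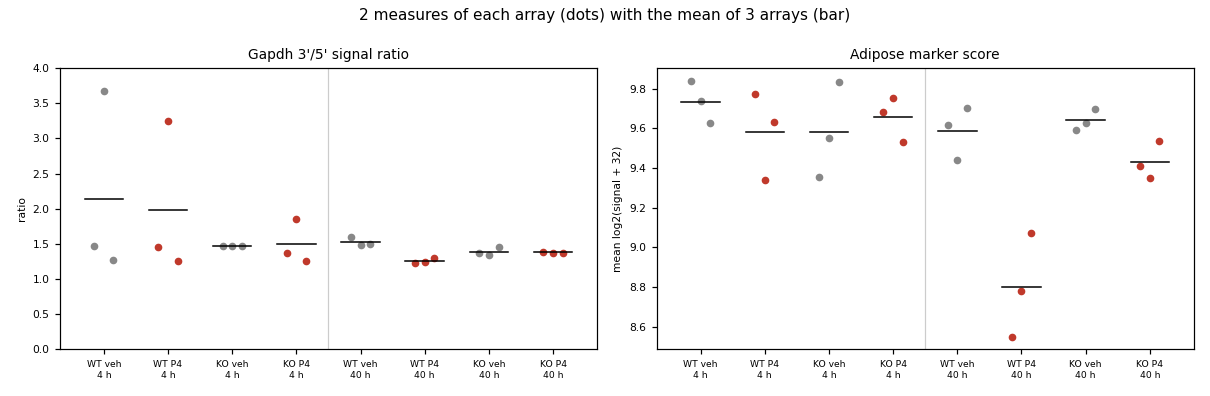
The Gapdh 3'/5' signal ratio (left) and the adipose score, the mean log2 of signal plus 32 over 11 markers (right), on each array. Dots are arrays (grey vehicle, red P4) and bars are the means of 3. Wild-type replicate 2 reached a ratio of 3.67 after vehicle and 3.25 after P4 at 4 h, and the adipose score averaged 8.80 in wild-type P4 uteri at 40 h.

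Across all probe sets, the P4 effects at 4 h and 40 h in wild-type uteri correlated weakly (Pearson r = 0.233, Spearman rho = 0.234 across genes, which are not independent replicates). The coefficient r was 0.115 without vehicle replicate 1 and 0.149 without P4 replicate 2 of the 4 h arrays. At both times 8 probe sets passed as higher and 6 as lower, where independent draws of the same sizes would share 0.466 and 0.189. The genes higher at both times included Acot7 and Npl, though Npl lost its 4 h call with a block for the replicate number (adjusted p = 0.0549, and 0.00336 to 0.689 over its alternatives). Those lower at both times included Tspan8, Efnb2, Car2 and Gjb2. The 4 probe sets that passed in opposite directions were those of Aldh1a1 (0.67 then −0.77), both of S100g, and that of Parm1 (0.49 then −0.61), the last chosen after its values were seen.

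The next question was whether the P4 response at 40 h in wild-type uteri differed from that at 4 h, tested directly as the difference of both effects. The calcium-binding protein genes S100g and Calb1 moved from a lower to a higher response, with time differences of 2.60 ± 0.24 and 2.11 ± 0.42. For Calb1 the 40 h rise itself, from a signal of 1519 ± 339 to 2388 ± 289 (SD, n = 3), did not pass. Spink1 (1.95 ± 0.25), Acod1 (1.36 ± 0.21) and the prostaglandin reductase Ptgr1 (1.09 ± 0.17) were also more responsive at 40 h. In PRKO uteri the P4 effects at 40 h, none of which passed, were 0.55 for Calb1 and 0.51 for Ptgr1. They were −0.21 for S100g, −0.06 for Spink1 and −0.13 for Acod1. Responses that were lower at 40 h were those of Cyp26a1 (−3.31 ± 0.22), whose P4 signal was back at 126.2 ± 8.99, and of Cited2 (−1.41 ± 0.21). They were also those of Adamdec1 (−1.84 ± 0.29), Inmt (−1.71 ± 0.28), Aldh1a1 (−1.44 ± 0.17), Sgk1 (−1.41 ± 0.26) and Scd1 (−1.38 ± 0.26). Other probe sets did not pass, at 0.39 for Acod1, 0.12 for Aldh1a1 and −1.05 and −0.09 for Scd1.

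By list, the time difference was positive for collagen and matrix genes. The 3 of 34 members that passed were Col3a1 (1.05 ± 0.23), Col1a2 (1.04 ± 0.21) and Col5a2 (0.65 ± 0.14), with 6 adjusted over the list alone (adjusted p = 1.43e-08, and adjusted p = 0.0503 with an estimated correlation). Other probe sets did not pass, at 1.08 and 1.12 for Col3a1 and −0.09 for Col1a2. Stroma markers (2 of 19, and 5 adjusted over the list alone) had an adjusted p of 7.31e-06, and adjusted p = 0.0556 with an estimated correlation. All 15 smooth muscle markers had a positive value, none of them passing and 3 adjusted over the list alone, and this list also passed with an estimated correlation (adjusted p = 1.29e-06 and 0.00218). Macrophage and dendritic cell markers (0 of 19; adjusted p = 0.00471) and oxidative phosphorylation genes (0 of 29; adjusted p = 0.0208) shifted up with no member adjusted over the list alone. They had adjusted p = 0.324 and adjusted p = 0.393 with an estimated correlation. The list of ribosomal proteins did not pass, but Rpl13a was higher (0.59 ± 0.12).

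The time difference was negative for the shared steroid hormone response (1 of 22, Sgk1, and 6 adjusted over the list alone), with an adjusted p of 1.97e-09. So it was for adipose markers (0 of 11, and 6 adjusted over the list alone), with an adjusted p of 2.18e-06. It was also negative for progesterone targets (adjusted p = 0.00346), where Cyp26a1 and Cited2 were lower and Acod1 higher among 30, and for retinoid metabolism genes (adjusted p = 0.0181), where Cyp26a1 and Aldh1a1 were lower among 15. Without both arrays of high Gapdh ratio the median of the progesterone targets went from −0.202 to −0.112 and the call was lost (adjusted p = 0.0953, and 0.000125 to 0.0953 over its alternatives). Adjusted over the list alone, 5 progesterone targets and 3 retinoid genes were lower and 1 of each was higher. Each of these 4 lists had an adjusted p = 0.0556 with an estimated correlation. Kallikreins (0 of 11, and 4 adjusted over the list alone; adjusted p = 0.000105) and class II genes (0 of 9, and 0 adjusted over the list alone; adjusted p = 0.0208) shifted down. With an estimated correlation these had adjusted p = 0.131 and adjusted p = 0.304. The class II, retinoid, oxidative phosphorylation and macrophage lists also lost their call when single arrays were left out, with the highest adjusted p, 0.334, for macrophage markers without vehicle replicate 3 at 4 h.

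By limma, 59 probe sets passed the test of the time difference, 27 with a higher and 32 with a lower response at 40 h, and 794 had an unadjusted p under 0.05. On the values as deposited, without rescaling, the split was 17 and 38. Without both arrays of high Gapdh 3'/5' ratio 38 passed, 21 higher and 17 lower, and 14 passed with the adipose score as a covariate. The count was 90 without P4 replicate 3 at 4 h, 36 and 38 without vehicle replicates 1 and 2 at 40 h, and 32 without P4 replicate 2 at 40 h. With the 12 arrays of these groups alone in the fit, 26 passed. With single arrays left out, Calb1, Scd1, Col3a1, Col1a2, Col5a2 and Rpl13a lost their call, at an adjusted p of up to 0.135.

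The same comparisons in PRKO uteri asked for P4 effects that do not pass through the receptor. Cyp26a1 had a P4 effect of −0.18 in PRKO uteri at 4 h, with signals of 129.3 ± 28.5 after vehicle and 108.8 ± 2.61 after P4 (SD, n = 3). At 40 h the PRKO effects of Spink1 and S100g were −0.06 and −0.21. Of the 20 genes named for wild-type uteri at 4 h, the PRKO values ran from −0.30 for Pla2g4a to 0.41 for Sult1d1. Of those named at 40 h, they ran from −0.32 for Scd1 to 0.25 for Ptger3, with Acta1 apart at 1.49.

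By limma, no probe set passed in PRKO uteri at either time, with 237 at an unadjusted p under 0.05 at 4 h and 831 at 40 h where chance would give 621.1. Of the 831, 236 were higher and 595 lower after P4. The median change over all probe sets was −0.042 in this comparison, and −0.011 with quantile normalization. A shift of whole arrays can therefore not be told apart from P4 effects in the 831. Without PRKO vehicle replicate 1, 2 probe sets passed at 4 h, and with the 6 arrays of the 40 h comparison alone in the fit 1 passed there. Of the 191 probe sets that passed in wild-type uteri at 40 h, 149 had the same sign in PRKO uteri, with a median of 0.126 in the wild-type direction against 0.627. For the 88 at 4 h the median was 0.00411 against 0.642, and 49 had the same sign.

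Some lists shifted in PRKO uteri by camera, none of them with an estimated correlation. At 40 h these were stroma markers (median 0.166; adjusted p = 1.44e-05), collagen and matrix genes (median 0.073; adjusted p = 0.000115), smooth muscle markers (median 0.074; adjusted p = 0.00494) and oxidative phosphorylation genes (median 0.108; adjusted p = 0.00815), all upward. With an estimated correlation their adjusted p was 0.128, 0.231, 0.0904 and 0.527. Adjusted over the list alone, 1 of 34 matrix genes was higher and none of 19 stroma, 15 muscle or 29 oxidative phosphorylation genes was. Kallikreins (median −0.155; adjusted p = 0.0102), the shared steroid hormone response (median −0.163; adjusted p = 0.0183) and chemokines and cytokines (median −0.085; adjusted p = 0.0195) shifted down. Each had adjusted p = 0.527 with an estimated correlation and no member adjusted over the list alone. These and oxidative phosphorylation genes also lost their call when single arrays were left out, at an adjusted p of up to 0.209. The adipose score of PRKO uteri at 40 h was 9.43 ± 0.09 (SD, n = 3) after P4 and 9.64 ± 0.05 after vehicle (exact two-sided permutation p = 0.1, the smallest possible, and 0.45 adjusted over 18 tests).

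At 4 h in PRKO uteri, 5 lists passed camera, each with an adjusted p of 0.0441 and no member passing over all probe sets or adjusted over the list alone. The shared steroid hormone response (median 0.05) and sterol and fatty acid synthesis genes (median 0.104) shifted up, with adjusted p = 0.571 and adjusted p = 0.455 with an estimated correlation. All 5 lists lost their call when single arrays were left out, with the highest adjusted p, 0.967, for the steroid list without PRKO P4 replicate 2. Cell cycle genes (median −0.056), epithelium markers (median −0.081) and smooth muscle markers (median −0.061) shifted down, with adjusted p = 0.493, adjusted p = 0.483 and adjusted p = 0.393 with an estimated correlation.

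**Figure D3:**
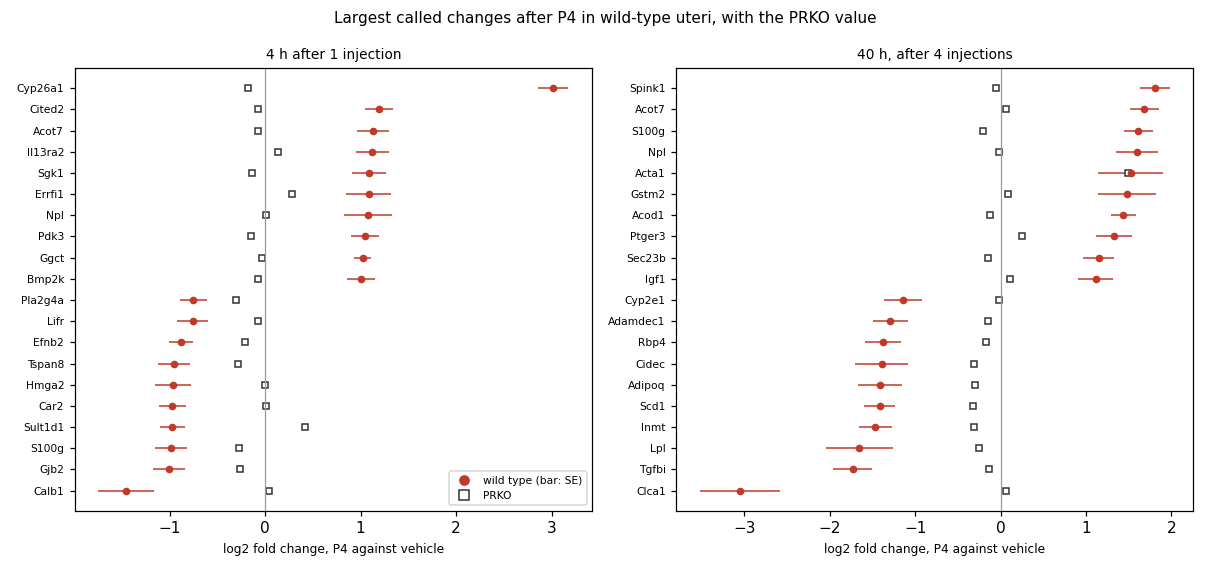
Log2 fold change after P4 of the 20 genes with the largest changes in wild-type uteri at 4 h (left) and at 40 h (right). Red dots with bars are wild-type values ± standard error, and open squares are the values of the same probe sets in PRKO uteri. Cyp26a1 lies at 3.02 in wild-type and −0.18 in PRKO uteri at 4 h, and Acta1 at 1.52 and 1.49 at 40 h.

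The genotype difference of the P4 effect asked directly which responses differed between wild-type and PRKO uteri. At 4 h Cyp26a1 differed most (3.20 ± 0.22, adjusted p = 3.37e-08), followed by Cited2 (1.27 ± 0.21), Pdk3 (1.19 ± 0.21), Bmp2k (1.07 ± 0.21) and Ggct (1.05 ± 0.13). Sult1d1, lower after P4 in wild-type uteri, had a difference of −1.39 ± 0.19. At 40 h the largest differences were those of Spink1 (1.87 ± 0.25), S100g (1.82 ± 0.24), Acot7 (1.63 ± 0.24), Acod1 (1.56 ± 0.21, and 0.55 at its other probe set, which did not pass) and Sec23b (1.29 ± 0.25, but 0.11 at its other probe set). The dipeptidase Cndp2 (−0.86 ± 0.16), the exchange factor Tiam1 (−0.62 ± 0.12) and the potassium channel Kcnq1 (−0.61 ± 0.12) differed downward, with −0.03 and 0.02 at the other probe sets of the last pair.

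By list, progesterone targets responded more in wild-type than in PRKO uteri at 4 h (2 of 30 members, Cyp26a1 and Cited2, and 7 adjusted over the list alone; adjusted p = 3.26e-05, and adjusted p = 0.0267 with an estimated correlation). Kallikreins (0 of 11, and 1 adjusted over the list alone; adjusted p = 0.00392) did so upward and matrix proteases and inhibitors (0 of 23, and 0 adjusted over the list alone; adjusted p = 0.0161) downward. With an estimated correlation these had adjusted p = 0.493 and adjusted p = 0.0663. At 40 h adipose markers (0 of 11, and 3 adjusted over the list alone) had a median difference of −0.63 (adjusted p = 1.65e-05, and adjusted p = 0.442 with an estimated correlation). Cell cycle genes (0 of 45, and 0 adjusted over the list alone) had a median difference of 0.123 (adjusted p = 0.0432, and adjusted p = 0.644 with an estimated correlation). The kallikrein, protease and cell cycle lists also lost their call when single arrays were left out (adjusted p up to 0.085, 0.0673 and 0.239). The collagen, stroma and smooth muscle lists did not pass this test.

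By limma, 12 probe sets passed the genotype difference at 4 h, 11 of them with a more positive response in wild-type uteri, and 13 at 40 h, 10 of them more positive. The 40 h split was 7 and 4 on the values as deposited, and it turned to 12 and 15 with a block for the replicate number and to 8 and 10 with the arrays of that time alone. Unadjusted p under 0.05 occurred 434 and 1130 times, where chance would give 621.1. Of the 1130 at 40 h, 770 had a more positive and 360 a more negative response in wild-type uteri. The median difference over all probe sets there was 0.035. All of the 12 and 13 also passed in wild-type uteri alone, a comparison that shares its arrays. The count at 4 h was 4 without both arrays of high Gapdh 3'/5' ratio and 1 when the fit held the arrays of that time alone. The count at 40 h was 0 with the adipose score as a covariate. At 4 h it was 4 without wild-type vehicle replicate 2, wild-type P4 replicate 1 or 2, PRKO vehicle replicate 3 or PRKO P4 replicate 1, 5 without PRKO vehicle replicate 2 or PRKO P4 replicate 3, and 42 without wild-type P4 replicate 3. At 40 h it was 32, 7 and 5 without wild-type vehicle replicates 1, 2 and 3, and 7 without wild-type P4 replicate 1 or 2. It was 7, 6 and 8 without PRKO vehicle replicates 1, 2 and 3, and 7 and 6 without PRKO P4 replicates 1 and 2. With single arrays left out, Cited2, Pdk3 and Bmp2k lost their call at 4 h and Sec23b, Cndp2, Tiam1 and Kcnq1 at 40 h, at an adjusted p of up to 0.153 and 0.166.

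The last question was how uteri without the receptor differed from wild-type uteri with no P4 given. Cdh16, which encodes a cadherin of epithelia, was higher in PRKO vehicle uteri, with a signal of 516.8 ± 136 against 184.7 ± 39.1 (SD, n = 3) at 4 h (1.32 ± 0.15) and a difference of 0.84 ± 0.15 at 40 h. The transcription factor gene Mycn was higher at both times at 1 probe set (0.76 ± 0.12 and 0.69 ± 0.12) and not at its other (0.05 and −0.04). Lower at both times were Sult1d1 (−1.44 ± 0.13 and −1.15 ± 0.13), the histamine-producing enzyme Hdc (−1.35 ± 0.23 and −1.36 ± 0.23), Lrp2 (−1.18 ± 0.20 and −1.40 ± 0.20) and the metallothionein Mt2 (−1.02 ± 0.18 and −0.95 ± 0.18). S100g was lower at 40 h at 1 probe set (−0.75 ± 0.14), and its other probe set, at −0.82, did not pass.

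Cell cycle genes were higher in PRKO vehicle uteri. At 4 h 4 of 45 members passed, the proliferation marker Mki67 (0.74 ± 0.14, and 0.40 at its other probe set), the topoisomerase Top2a (0.66 ± 0.12), Cks2 (0.65 ± 0.13) and the replication factor Mcm3 (0.42 ± 0.08, and 0.39 at its other probe set). Adjusted over the list alone 6 passed, and the median was 0.137 (adjusted p = 4.88e-14, and adjusted p = 0.0063 with an estimated correlation). At 40 h the median was 0.083 with no member passing, over all probe sets or adjusted over the list alone (adjusted p = 1.51e-09, and adjusted p = 0.0231 with an estimated correlation). The replication-associated gene Pclaf was also higher at 4 h at 1 probe set (0.71 ± 0.09, but 0.13 and −0.04 at its others), as were the collagen Col18a1 (0.67 ± 0.14 at 1 of 5 probe sets), the plasminogen activator Plat (0.43 ± 0.09) and the Wnt receptor Fzd6 (0.42 ± 0.09). Fzd6 lost its call with a block for the replicate number (limma adjusted p = 0.0549). The cell cycle list kept its call at both times when any single array was left out. The Gapdh 3'/5' ratio was 2.14 ± 1.33 (SD, n = 3) in wild-type and 1.47 ± 0.002 in PRKO vehicle uteri at 4 h, and without the wild-type array of high ratio the list median was 0.179.

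Progesterone targets were lower in PRKO vehicle uteri at 4 h, where 2 of 30 members, Hdc and Lrp2, passed and, adjusted over the list alone, 2 were lower and 1 higher (adjusted p = 9.37e-05, and adjusted p = 0.0292 with an estimated correlation). Without wild-type replicate 3 its adjusted p was 0.0808. The same 2 members passed at 40 h, also adjusted over the list alone (adjusted p = 0.0351, and adjusted p = 0.293 with an estimated correlation). Retinoid metabolism genes shifted up at both times with none of 15 passing, over all probe sets or adjusted over the list alone (adjusted p = 0.00956 and 0.00529, and adjusted p = 0.0491 and 0.0231 with an estimated correlation). The call at 4 h was lost without wild-type replicate 1 or 2 or PRKO replicate 1 (adjusted p up to 0.128). The shared steroid hormone response shifted down at both times with Mt2 the member that passed and 2 adjusted over the list alone (adjusted p = 9.37e-05 and 0.0171, and adjusted p = 0.217 and 0.598 with an estimated correlation).

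Lists of other cell types and of stress shifted in PRKO vehicle uteri with the preset correlation alone, and no single member of them except Hdc passed. At 4 h endoplasmic reticulum chaperones (0 of 18; adjusted p = 0.00325), macrophage markers (0 of 19; adjusted p = 0.00348), class II genes (0 of 9; adjusted p = 0.00348) and adipose markers (0 of 11; adjusted p = 0.0193) were lower. Epithelium markers (0 of 22; adjusted p = 0.0133) were higher. With an estimated correlation these had adjusted p = 0.217, 0.265, 0.217, 0.419 and 0.222. Adjusted over the list alone 1 macrophage marker was lower and no member of the others passed. At 40 h neutrophil and eosinophil markers (0 of 16, and 0 adjusted over the list alone; adjusted p = 0.0215) and mast cell markers (1 of 11, Hdc, also adjusted over the list alone; adjusted p = 0.032) were lower. With an estimated correlation these had adjusted p = 0.45 and 0.451. Each of these lists, the steroid list at both times and the progesterone list at 40 h lost its call when some single array was left out. The highest adjusted p was 0.612 without wild-type replicate 3 at 4 h and 0.624 without wild-type replicate 1 at 40 h. The Gapdh 3'/5' ratio at 40 h was 1.39 ± 0.06 (SD, n = 3) in PRKO and 1.53 ± 0.06 in wild-type vehicle uteri (exact two-sided permutation p = 0.1, the smallest possible, and 0.45 adjusted over 18 tests).

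By limma, 23 probe sets passed between the genotypes in vehicle uteri at 4 h, 19 higher and 4 lower in PRKO, and 8 at 40 h, 2 higher and 6 lower, with 623 and 382 at an unadjusted p under 0.05 where chance would give 621.1. Of these, 6 passed at both times in the same direction, where independent draws would share 0.00306 upward and 0.00193 downward, and all 23 had the same sign at 40 h. Without both arrays of high Gapdh 3'/5' ratio 14 passed at 4 h, with the split at 7 and 7, and among the brightest 8281 and 6211 probe sets it was 5 and 4 and then 0 and 2. With the adipose score as a covariate 10 and 3 passed at 4 h and 40 h. At 4 h the count was 14 (7 higher and 7 lower) and 3 without wild-type replicates 2 and 3 and 14, 3 and 13 without PRKO replicates 1, 2 and 3, and it was 1 with these 6 arrays alone in the fit. At 40 h it was 4 and 2 without wild-type replicates 1 and 2 and 2, 3 and 1 without PRKO replicates 1, 2 and 3, and it was 2 with these 6 arrays alone in the fit. With single arrays left out, every gene named above between the genotypes in vehicle uteri lost its call except Cdh16, Pclaf and Sult1d1 at 4 h and Sult1d1 at 40 h, at an adjusted p of up to 0.312 and 0.421.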

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

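The tests of a receptor-dependent change for the adipose and matrix genes, the epithelium test, both covariate fits and the sorting of regroupings by what they keep were chosen after the results had been seen.

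Adipose markers were lower in wild-type uteri 40 h after the first P4 injection, with Car3 at a signal of 2377 ± 916 (SD, n = 3) against 5007 ± 466, Lpl at 1692 ± 557 against 3837 ± 328 and Adipoq at 884.4 ± 439 against 2251 ± 395. With the Gapdh ratio as a covariate the list median kept 108% of its size (−0.84 to −0.91). This does not exclude RNA quality, since the ratio separated the wild-type P4 and vehicle arrays at 40 h. The slope of the ratio also rests largely on the 2 wild-type arrays at 4 h with ratios of 3.67 and 3.25. A candidate explanation is less fat attached to the dissected uteri, since over the other 21 arrays the within-group deviations of the 10 other markers, of which Lpl is also expressed outside fat, tracked those of Adipoq (Pearson r = 0.799, permutation p = 0.00062, Spearman rho = 0.781, permutation p = 0.001, and r = 0.704 without the 2 arrays farthest in Adipoq). With the adipose score as a covariate no call was left, since errors rose (median 0.102 to 0.178) and changes kept a median of 81.2% over the 191 calls (from 1.81 ± 0.17 to 1.11 ± 0.24 for Spink1, 99.2% for Tgfbi, 92.9% for Acot7 and 25.1% for Rbp4), while that of Adipoq (−1.41 ± 0.25 to 0.03 ± 0.22) is removed by construction as part of the score. A change that needs the receptor cannot be told apart from less fat on the wild-type P4 uteri, since either gives a genotype difference of this list (median −0.63, adjusted p = 0.442 with an estimated correlation).

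Cell cycle genes were higher in PRKO than in wild-type vehicle uteri at both times, with means over the list of 0.183 at 4 h and 0.106 at 40 h. RNA quality of the wild-type array with a Gapdh ratio of 3.67 is not the whole of it, since the list median at 4 h was 131% of its size without that array (0.137 to 0.179). At 40 h the epithelium markers as a set argue against a higher share of epithelium. Their mean difference was −0.07 (95% interval over genes −0.18 to 0.04, upper bound −0.0668 from the cell cycle mean). The cell cycle interval was 0.07 to 0.141. Of the markers, 8 lay above 0 and 14 below, and their median was under the cell cycle mean by 0.153. Their SD of 0.245 describes single markers and not their mean. Genes of a list are not independent, so the intervals are too narrow to exclude a higher share. At 4 h a higher share cannot be told apart. The epithelium interval there, −0.01 to 0.22, includes the cell cycle mean, and the epithelial cadherin gene Cdh16 was higher at both times (1.32 ± 0.15 and 0.84 ± 0.15). A higher rate of division in uteri without the receptor is untested beside a higher share of epithelium, since no cells were counted here.

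Collagen and matrix genes were higher after P4 at 40 h, with a mean over the list of 0.252 in wild-type and 0.122 in PRKO uteri, where the list did not pass with an estimated correlation (adjusted p = 0.231). With the adipose score as a covariate the wild-type median of the matrix list became 127% of its size (0.245 to 0.31), while that of stroma markers went from 0.333 to 0.196. With the Gapdh ratio the matrix median kept 102% (0.245 to 0.251). The matrix median thus did not shrink in either fit. Neither less adipose tissue nor RNA quality is excluded by this, since both measures separated the wild-type P4 and vehicle arrays at 40 h. Whether the change needs the receptor cannot be told apart from a response of both genotypes: the mean genotype difference was 0.13, with a 95% interval over genes of 0.0534 to 0.207, whose upper bound lies under the wild-type mean but above 50% of it, and camera did not pass. A part that does not need the receptor may be present, since the PRKO mean of 0.122 had a 95% interval over genes of 0.0487 to 0.195. Genes of a list on the same arrays are not independent, so these intervals are too narrow to settle its size. The adipose score also separated the PRKO P4 and vehicle arrays at 40 h (9.43 ± 0.09 against 9.64 ± 0.05, SD, n = 3). Less adipose tissue is therefore not excluded for the PRKO rise either.

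Responses to P4 differed between wild-type and PRKO uteri by the test of the difference itself for 12 probe sets at 4 h and 13 at 40 h. At 4 h the differences were 3.20 for Cyp26a1, 1.27 for Cited2, 1.19 for Pdk3, 1.07 for Bmp2k, 1.05 for Ggct and −1.39 for Sult1d1. At 40 h they were 1.87 for Spink1, 1.82 for S100g, 1.63 for Acot7, 1.56 for Acod1, 1.29 for Sec23b, −0.86 for Cndp2, −0.62 for Tiam1 and −0.61 for Kcnq1. By list, the median differences at 4 h were 0.108 for progesterone targets, −0.142 for matrix proteases and inhibitors and 0.218 for kallikreins, and at 40 h they were 0.123 for cell cycle genes and −0.627 for adipose markers. Only the progesterone targets also passed with an estimated correlation (adjusted p = 0.0267), and the others in this order had adjusted p = 0.0663, 0.493, 0.644 and 0.442.

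As many probe sets passed the genotype difference in 20 of 100 regroupings at 4 h (up to 3160) and 10 of 100 at 40 h (up to 127), the real grouping included. By the rule written beforehand, chance is set aside only at a share under 0.05, and neither share lay under it. At 4 h, 11 of the 83 that mixed the treatments in both genotypes reached the count, 3 of them among the 23 that parted all wild-type numbers, which pair (up to 609), so chance is not excluded. With the replicate block the count was 27 against 12. At 40 h all 9 others that reached the count kept the real treatment groups of at least 1 genotype and so carry its effect, and 0 of 79 that mixed both did (up to 10), so the full share does not decide about chance.

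Responses to P4 in wild-type uteri differed between 4 h and 40 h by the test of the difference itself for 59 probe sets. The count was reached by 5 of 100 regroupings, the real one included (up to 107). By the rule written beforehand, which sets chance aside only at a share under 0.05, chance was not set aside. The other 4 regroupings that reached the count kept the real groups of at least 1 time and so carry its effect. Of the 78 that mixed both times, 0 called any, so the full share does not decide about chance. The differences of genes named by the rule, which asks for parted 40 h arrays, were 2.60 for S100g, 2.11 for Calb1, 1.95 for Spink1, 1.36 for Acod1, 1.09 for Ptgr1, −1.84 for Adamdec1, −1.71 for Inmt, −1.44 for Aldh1a1, −1.41 for Sgk1 and −1.38 for Scd1. Outside it, Cyp26a1 (−3.31) and Cited2 (−1.41) passed as members of lists. Median differences by list were −0.202 for progesterone targets, −0.468 for the shared steroid hormone response, 0.281 for stroma, 0.274 for smooth muscle, 0.141 for macrophage and dendritic cell markers and −0.149 for class II genes. They were −0.039 for retinoid metabolism, 0.234 for collagen and matrix, −0.258 for kallikreins, 0.099 for oxidative phosphorylation and −0.862 for adipose markers. Only smooth muscle also passed with an estimated correlation (adjusted p = 0.00218), and the others had adjusted p = 0.0503 to 0.393.

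For comparisons of 3 arrays with 3, the 10 splits are too few to give a share under 0.05. The real wild-type count at 4 h was 88 and the highest other split called 364, with 2 of 10 as large. At 40 h it was 191 against 0, with 1 of 10 as large. Between genotypes in vehicle uteri the counts were 23 against 974 at 4 h (2 of 10) and 8 against 0 at 40 h (1 of 10). In PRKO uteri the real count was 0 at both times, so all 10 of 10 splits were as large, with highest others of 679 at 4 h and 0 at 40 h. Splits that call several times the real count point to a structure of the 4 h arrays beside their groups. The first component of variation within groups held 41.7% of the within-group variance at 4 h and 34.2% at 40 h. For the wild-type 4 h arrays, whose numbers pair, the highest other split put vehicle replicates 1 and 3 with P4 replicate 3, and the other splits that part all pairs, of 4 in all, called 0.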

How the results depend on the processing

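The omission of both arrays of high Gapdh ratio and both covariate fits were chosen after the data were seen. Counts within 1.5 times their reported value under an alternative are not repeated here.

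With an offset of 100 the genotype difference at 4 h had 19 calls. Among the brightest 8281 probe sets the genotype difference at 40 h had 7 and PRKO against wild type at 4 h had 9. Among the brightest 6211 these had 5 and 2, and PRKO against wild type at 40 h had 1, with fewer genes tested. Requiring at least 1.5-fold left 51 and 108 for wild-type P4 at 4 h and 40 h and 12 for PRKO against wild type at 4 h, by construction. With the arrays of the same time alone, wild-type P4 had 29 calls at 4 h and 539 at 40 h, the genotype difference at 4 h 1, and PRKO against wild type 5 and 13. The spread was then estimated from the 12 arrays of that time. Its median within groups was higher at 4 h (SD 0.111 to 0.147) than at 40 h (0.0767 to 0.0974). With the compared groups alone, wild-type P4 at 4 h had 10, PRKO P4 at 40 h 1, the genotype difference at 4 h 1, PRKO against wild type 1 and 2, and the time difference 26, with fewer samples.

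With the replicate block, wild-type P4 at 40 h had 386 calls, the genotype differences 27 and 27, PRKO against wild type at 40 h 13, and the time difference 112. For wild-type P4 at 4 h, where every pair of a number correlated above 0.1, the block gave 128 against 88. At 40 h P4 arrays also matched the vehicle array of their own number best, more weakly in wild-type uteri (0.0686 to 0.142). The cause was not tested.

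Without both arrays of high Gapdh ratio, wild-type P4 at 4 h had 29, the genotype difference at 4 h 4, PRKO against wild type at 4 h 14 and the time difference 38, with fewer samples. With the Gapdh ratio as a covariate, wild-type P4 at 40 h had 369 and the genotype differences 21 and 39, and the cause was not tested. With the adipose score as a covariate, wild-type P4 at 40 h and the genotype difference at 40 h had 0 (limma; 562 unadjusted p under 0.05 for the first, where chance would give 621.1), PRKO against wild type 10 and 3, and the time difference 14. In that fit Lpl (0.235), Adipoq (0.030), Cidec (0.125) and Fasn (0.074) changed sign in wild-type P4 at 40 h, and the median of the adipose list, from which the score is made, was −0.032 there, near 0 with camera's direction turned, and 0.043 for the time difference. The correlation between wild-type effects at 4 h and 40 h was 0.185 without both arrays, 0.282 with the Gapdh ratio and 0.306 with the adipose score, and 0.115 to 0.252 when each array was left out.

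Leaving out each array, a group of 2 being assumed to vary like the others, gave 41 to 138 calls for wild-type P4 at 4 h, 90 to 189 at 40 h, 0 to 2 for PRKO P4 at 4 h and 0 at 40 h. It gave 4 to 42 and 5 to 32 for the genotype differences, 3 to 24 and 1 to 9 for PRKO against wild type, and 32 to 90 for the time difference. Named genes that passed in every omission were 14 of 20 for wild-type P4 at 4 h and 15 of 20 at 40 h. They were 3 of 6 and 4 of 8 for the genotype differences, 3 of 9 and 1 of 7 for PRKO against wild type, and 8 of 10 for the time difference. Those that passed under every alternative they could be tested in, covariates included, were 5, 0, 1, 0, 1, 1 and 3 in the same order, and dim genes are absent from the brightest sets. The shared steroid list in PRKO uteri at 4 h turned its camera direction without PRKO P4 replicate 2 while its median stayed above 0 (0.038 against 0.05, adjusted p = 0.967, with medians of −0.013 to 0.202 over the omissions).

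Over all alternatives, named genes counted as unchanged in 3318 instances, lost the call in 472, gained it in 7 and reversed in 4. The unchanged instances include genes that passed neither in the main fit nor in the alternative, such as Pgr, whatever their sign. They are therefore not a count of calls that were kept. Lists kept direction and call in 1068 instances, lost the call in 217 and reversed by camera's direction in 3. No scaling moved the median of all probe sets by over 0.1. The offset compresses changes at low signal, where Pgr lies (percentile 22.4).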

Other observations

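The Pgr stretch test was written before its result was seen, except for the interval of its percentile, which the written rule did not hold. The observations on single genes were made after their values were seen.

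Genes of the P4 response at both times in wild-type uteri that the rule for named genes did not reach include the chloride channel Clcn5 (0.70 ± 0.12 at 4 h and 0.71 ± 0.12 at 40 h, but 0.07 and −0.06 at its other probe set) and the innate immune adaptor Myd88 (0.82 ± 0.17 and 0.73 ± 0.17). With them rose the glucose transporter Slc2a3 (0.53 ± 0.12 and 0.72 ± 0.12, and 0.07 and 0.50 at its other) and the homeodomain protein gene Hopx (0.45 ± 0.09 and 0.56 ± 0.09). Among the 12 probe sets with a genotype difference at 4 h were also Pip5k1b (1.00 ± 0.15, but 0.07 at its other probe set), Caprin2 (0.96 ± 0.18), Tiparp (0.89 ± 0.17), Atp6v1b2 (0.55 ± 0.10, and 0.69 at its other, which did not pass) and both probe sets of the alcohol dehydrogenase Adh5 (0.70 ± 0.12 and 0.63 ± 0.12). At 40 h they included the lipoxygenase Alox12e (0.87 ± 0.14) and Pcmt1 (0.47 ± 0.09), whose other probe sets did not pass (0.52 for Alox12e, and 0.12 and 0.17 for Pcmt1).

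Lrp2 and Hdc had their lowest signals in PRKO uteri, treated or not. Lrp2 had a signal of 459 ± 171 (SD, n = 3) in wild-type vehicle uteri at 40 h and 992 ± 106 after P4, against 148 ± 17.1 and 164.6 ± 16.7 in PRKO uteri. Hdc had 1197 ± 444 and 2009 ± 245 against 433.4 ± 96.8 and 658.6 ± 85.7, with P4 effects of 0.79 ± 0.23 (adjusted p = 0.0906) and 0.58 ± 0.23 (adjusted p = 0.703), neither of which passed. Sult1d1 was lower in PRKO vehicle uteri (153.6 ± 28.1 against 468.2 ± 34.3 at 4 h) and was also lower after P4 in wild-type uteri at 4 h (223.8 ± 35.6), both comparisons sharing the wild-type vehicle arrays.

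PRKO and wild-type uteri could differ through a stretch of chromosome around Pgr carried with the targeted allele. Over the 16 measured genes below and 50 above Pgr, the median absolute test statistic of the genotype difference lay at percentile 71.7 of 6841 like stretches, and 0 probe sets there passed at either time. By the rule written beforehand, which used the percentile alone and 50 genes on either side, this value counts against a carried stretch. The interval of that percentile over the stretch's own genes, which the rule did not hold, was 0.965 to 98.2. It is too wide to decide.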
